A study of Oryza sativa Japonica Group with 96 samples.

How the data were processed

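Gene expression was measured on 96 single-sample Affymetrix arrays of rice stem bases, the part of the seedling from which crown roots emerge. The plants were the crl1 mutant of cultivar Taichung 65, transformed with the vector pINDEX2 either empty (line DX) or carrying the CRL1 gene under control of dexamethasone (line DXC). Per the labels' protocols, seedlings were grown for 5 days in dishes with 14 h of daylight, rested for 24 h in flasks, and received 1 µM dexamethasone, which was removed after 5 h by a change of medium. Stem bases were collected every 3 h from 0 to 45 h in 3 independent experiments, each pooling several stem bases per sample. RNA was labelled as biotinylated single-strand cDNA with the Affymetrix WT PLUS protocol, per the labels' protocols.

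The deposited table held log2 expression values of 36643 features, 1 column per array, already normalized by the authors. The submitters' processing notes name GCRMA, which corrects background from probe sequence, normalizes probes between arrays and summarises them per feature; its version and settings are not given in the sources used here. The values ran from 1.82 to 12.92, array medians from 4.62 to 4.76, and the SD over features of an array from 1.40 to 1.68. Scanner files were not used here, so no background level or detection call stands behind a value, and the number of arrays limits the precision. The number of columns without a sample was 0. The highest correlation between 2 arrays was 0.989 and the lowest SD of the differences between 2 arrays was 0.219, so no array was taken for a copy of another.

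The platform annotation gave 1 gene symbol to 24161 features, several to 90 and none to 12392. These 24161 were found by gene number in the RefSeq gene table of assembly ASM3414082v1, which was used only for synonyms, biotypes and the order of genes; 2744 of the features had a gene with a name other than a LOC symbol. No feature could be tied to CRL1 or to the CRL1-like gene by these tables, so the induced transgene was not analysed here. Features with several symbols were named in no result.

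The 32 groups of line and hour, 3 arrays each, were fitted together with limma (lmFit, then eBayes with an intensity trend; 64 residual degrees of freedom), so that all groups shared 1 estimate of the spread per feature. Contrasts were DXC minus DX at 0 h, at each hour from 3 to 45 h with 1 adjustment over all features and hours, and over 3 windows. The early (3 to 9 h), middle (12 to 24 h) and late window (27 to 45 h) were each taken minus the 0 h difference. The single hours were not. Moderated F tests of 15 contrasts asked for a line by time interaction and for a time effect within each line. Each adjusted p is a Benjamini-Hochberg value from limma, and a feature was called under 0.05. Differences are on the log2 scale with the standard error (SE) of the fit, and group levels are means with the SD over 3 experiments.

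Lists of genes were fixed before the data were examined, as 31 themes matched to gene symbols and synonyms; the symbols were chosen after the annotation was read and before any comparison of expression. Camera (limma) compared each list of at least 3 features with all other features, two-sided, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 84 tests (28 lists in 3 windows). The LBD family (1 feature), AP2/PLETHORA family (0 features) and auxin synthesis (2 features) lists were too small to test. The tested lists were crown root regulators, WOX family, Aux/IAA, ARF, GH3 and SAUR, auxin transport, type-A response regulators, cytokinin metabolism, gibberellin metabolism, core histones, mitotic cyclins and CDKB, D-type cyclins, DNA replication, cytosolic ribosomal proteins, wall loosening (expansins, XTH), class III peroxidases, secondary wall, HD-ZIP and ROC, SCARECROW and SHORT-ROOT, ROP signalling, KNOX (shoot meristem), photosynthesis (leaf), seed storage and amylase (seed remains), jasmonate, heat shock, hypoxia, pathogenesis-related and clock.

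Genes named in the text followed a rule fixed before the data were examined. For each window it took the 10 higher and 10 lower called features with the largest difference, 1 gene each and the same sign in all 3 experiments, and at 0 h the 5 higher and 5 lower. For the time effect in DX it took the 5 features with the largest range of hourly means. It also took every member of the crown root and clock lists and up to 4 members of each other list with the lowest p.

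The series design text states that the replicate numbers mark independent experiments, so equal numbers pair the lines. Counts with the experiment as a block are given beside most of the results they change. In 48 pairs of arrays of 1 hour and number, deviations from the group means correlated by 0.05 on average, against -0.03 for other numbers; 16 pairs exceeded 0.1 and the lowest was -0.64. Array summaries also moved in sets of 4 consecutive hours (0 to 9, 12 to 21, 24 to 33 and 36 to 45 h) of 1 line and experiment, 24 sets in all. These sets entered a further fit as a random block (consensus correlation 0.439), an alternative chosen after seeing the data, and as a fixed block for the early window, which lies within 1 set together with 0 h. The contrast of the early with the late window was also added after seeing the data.

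Other alternatives were quantile normalization, centring of array medians, leaving out the 40% of features with the lowest mean, eBayes without the trend, leaving out each experiment, no subtraction of the 0 h difference, and only the arrays of the hours in a contrast. The fits were tested on simulated data with the spread of the 36643 features and 200 features changed, 100 by each size. Of features changed by 1 log2 unit, 59% were called in the early, 65% in the middle and 65% in the late window, 71% at 0 h, 68% by the interaction (change in the early window) and 60% at any hour (change at 6 h). For a change of 0.5 the shares were 9%, 15%, 14%, 14%, 12% and 3%. The time effect recovered 94% of changes of 1 and 52% of changes of 0.5 in DX, and 92% and 59% in DXC; the contrast of early with late recovered 90% and 43%. A shift of 0.5 given to 3 lists was called for 3 of them, with 0 calls among the other lists. In these simulations the errors were independent between features and between arrays. The shares thus hold for arrays without set effects. False calls of lists with correlated members were not tested by them, and the estimated correlation in the data was 0.762 for the ribosomal list. Calculations used R 4.3.3, limma 3.58.1, statmod 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.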

Results

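The transcriptome of rice stem bases was followed for 45 h after a pulse of dexamethasone in 2 lines of the crown rootless mutant crl1. DXC carried CRL1, a transcription factor gene required for crown root formation, under the control of dexamethasone, and DX carried the empty vector, so that DX gave the response to the inducer and to the change of medium alone. Each line was sampled at 16 hours in 3 experiments, which gave 48 arrays per line and 3 per line and hour. The median correlation between arrays of a group was 0.964. The study asked which transcripts followed the ectopic expression of CRL1, and each window is therefore given as the difference DXC minus DX minus the same difference at 0 h. Rose and fell, where said of a window, refer to this difference and not to the level in DXC alone. The induced gene itself comes first in such a design, but the annotation used here ties no feature to CRL1 or to its neighbour CRL1-like, and their values were not analysed here.

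**Figure D1:**
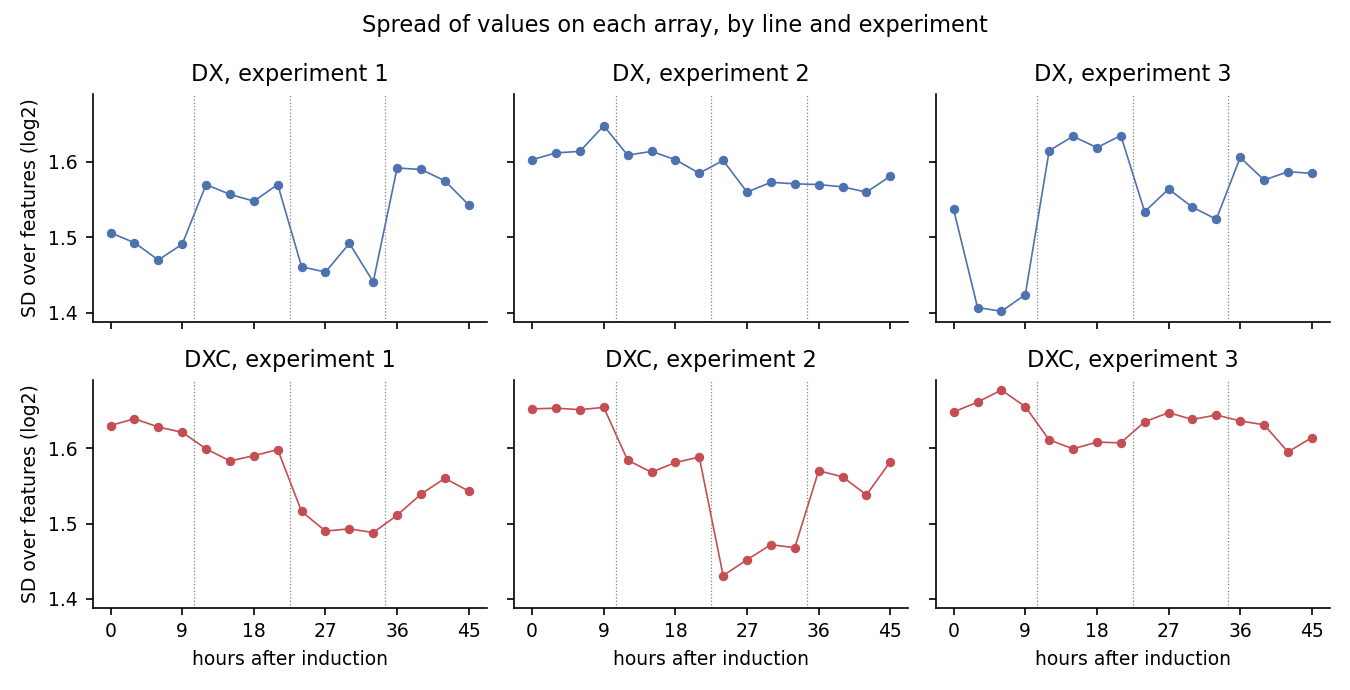
SD over all features of each array (y axis, log2) against hours after induction (x axis), a panel per line and experiment, with DX in blue and DXC in red; dotted lines part sets of 4 consecutive hours. At 0 to 9 h the mean was 1.65 in DXC and 1.52 in DX.

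Before induction few transcripts were called different between the lines, in a comparison that recovered 14% of simulated changes of 0.5 log2 units. LOC4331398 was 4.62-fold higher in DXC at 0 h (8.18 ± 0.12 against 5.97 ± 0.65, mean log2 ± SD, n = 3; adjusted p = 0.00205), and LOC4333329 was 2.12-fold higher (adjusted p = 0.00399). LOC9266913 was 2.44-fold lower (3.85 ± 0.11 against 5.14 ± 0.09; adjusted p = 2.3e-06), LOC4341605 was lower by a difference of -1.08 (adjusted p = 0.0368) and LOC4339955 by -0.79 (adjusted p = 0.0201). LOC4331398 and LOC9266913 stayed apart, being called at all 15 later hours. In all, 10 features differed at 0 h, 4 higher and 6 lower in DXC, and 4763 had an unadjusted p under 0.05. With the experiment as a block 19 features were called, and with array sets as a random block 36. The limma count was 2 without experiment 1, 0 without experiment 2 (4334 at an unadjusted p under 0.05) and 6 without experiment 3, and 3 in a fit of the 0 h arrays alone, in which none of the 5 named genes was called (adjusted p from 0.0863 to 0.323). Without experiment 2 the adjusted p of LOC4331398 was 0.0811 and that of LOC9266913 was 0.0584, and without experiment 1 that of LOC4331398 was 0.273.

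In the early window, 3 to 9 h, induction of DXC was mostly followed by higher transcript levels. The largest change was that of LOC9271993, a protein-coding gene of unnamed function, which was 36.6-fold higher than in DX relative to 0 h (log2 difference 5.19, SE 0.46, n = 3 experiments; adjusted p = 7.88e-13). Its level in DXC went from 4.12 ± 0.14 at 0 h to 8.31 ± 0.46 at 3 h and 9.99 ± 0.29 at 6 h, while DX stood at 4.72 ± 0.33 at 6 h. No feature was tied to CRL1 or CRL1-like, so whether LOC9271993 is 1 of these genes or responded to the induction could not be told. LOC4330584 rose later, from 4.73 ± 0.13 at 3 h to 9.77 ± 0.42 at 9 h, 27.6-fold above DX at 9 h (adjusted p = 2.33e-12). Over the window its difference was 2.72 (adjusted p = 0.000821, but 0.0944 without experiment 1 and 0.252 without experiment 2). LOC4336268 was 5.13-fold higher over the window (adjusted p = 4.15e-07) and LOC4351404, annotated as a transcribed pseudogene, 7.26-fold (adjusted p = 9.41e-05, but 0.123 without experiment 2).

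**Figure D2:**
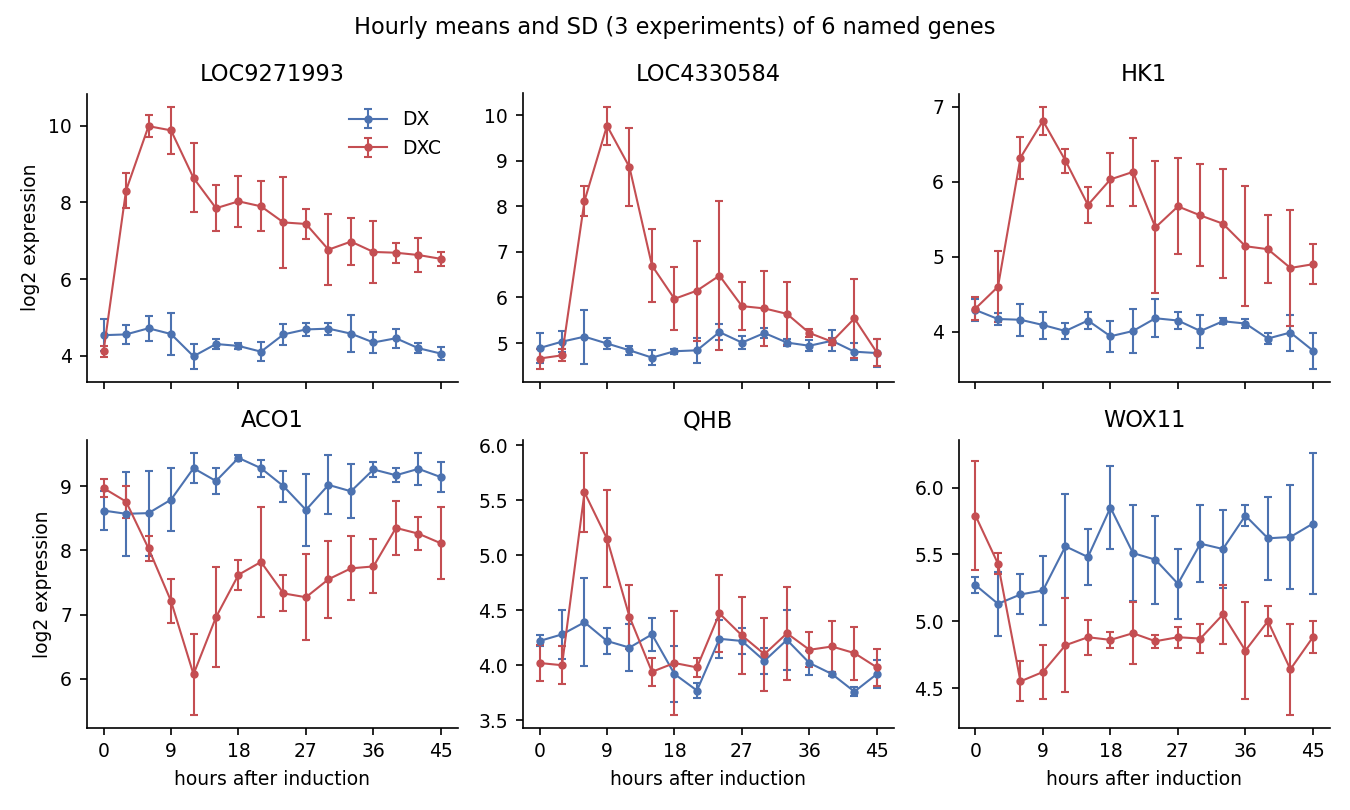
Log2 expression (y axis) against hours after induction (x axis) for 6 named genes in DX (blue) and DXC (red); points are means and bars SDs of 3 experiments. LOC9271993 reached 9.99 in DXC at 6 h and LOC4330584 9.77 at 9 h, ACO1 had its lowest mean, 6.07, at 12 h, and QHB was highest, 5.57, at 6 h.

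The other leading genes of the early window were LOC4324857 (difference 2.94), LOC4330827 (2.88), LOC9269942 (2.85), LOC4332560 (2.58), LOC4329444 (2.50) and LOC4349090 (4.59-fold), with adjusted p from 2.41e-05 to 0.00062. For LOC4324857 and LOC4330827 part of the difference lay at 0 h, where LOC4324857 stood at 4.21 ± 0.35 in DXC and 5.09 ± 0.61 in DX, and LOC4330827 at 3.94 ± 0.14 and 5.33 ± 1.44. Among genes of the fixed lists, GH3.1, which encodes an auxin-conjugating enzyme, rose by 1.26 (adjusted p = 0.011), the homeobox gene Hox13 by 1.11 (adjusted p = 0.0275; with Hox21 the 2 called of 34 HD-ZIP and ROC features, 3 adjusted over the list alone) and RFC1, a subunit of the clamp loader of DNA replication, by 0.86 (adjusted p = 0.0218). None of these 3 was called without experiment 2 (adjusted p = 0.757, 0.762 and 0.406) and none without experiment 1 (0.0658, 0.275 and 0.459), nor RFC1 without experiment 3 (0.0994).

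Lower values in the early window were small and less firm. Hox21, a homeodomain-leucine zipper gene, had a difference of -0.72 (adjusted p = 0.0244), of which -0.49 lay in the window and the rest at 0 h. DXC went from 8.09 ± 0.12 at 0 h to 7.22 ± 0.10 and DX from 7.87 ± 0.23 to 7.71 ± 0.03. LOC4342612 had -0.71 (adjusted p = 0.0111), with a change from 0 h of -0.37 in DXC and of 0.34 in DX. LOC4341603 (-0.66) and LOC4342422 (-0.50) were also called lower. For 6 of the 8 named lower genes, LOC4342612 and LOC4342422 among them, the larger part of the value was the difference at 0 h. LOC4342422 stood at 4.62 in DXC and 4.30 in DX at 0 h, and at 4.36 and 4.54 in the window. None of Hox21, LOC4342612, LOC4341603 and LOC4342422 was called when any 1 experiment was left out (adjusted p from 0.0944 to 1), and none of the 8 in a fit of only the hours 0 to 9 (0.204 to 0.483). LOC4345971 (-0.73), LOC4327639 (-0.68), LOC4347765 (-0.60) and LOC4330828 (-0.60) were called lower too, but their largest difference between the lines at any hour was at 0 h, where DXC was the higher line.

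In this window 122 features were called, 113 higher and 9 lower in DXC. The 113 had a median difference between the lines of -0.10 at 0 h, 0.37 at 3 h, 1.49 at 6 h, 1.55 at 9 h, 0.78 at 12 h and 0.21 at 45 h. With the experiment as a block 184 features were called (167 higher, 17 lower), with array sets as a random block 802 (578 higher, 224 lower), and with the sets as a fixed block, which leaves only differences within a set, 1271 (902 higher, 369 lower). The count was 47 without experiment 1, 4 without experiment 2 and 55 without experiment 3. Several differences that were no longer called without experiment 2 had kept their size, with 3.08 for LOC4351404, 2.72 for LOC4330584, 2.59 for LOC9269942 and 2.48 for LOC4329444, while the others were smaller, with 2.04 for LOC4330827 (adjusted p = 0.125), 2.36 for LOC4324857 (0.303), 1.93 for LOC4349090 and 1.91 for LOC4332560. LOC9271993 and LOC4336268 were the 2 of the 18 named genes that were still called without experiment 2. A fit of only the hours 0 to 9 gave 46, and LOC4332560 was not called there (adjusted p = 0.0948). Without the subtraction of the 0 h difference 22507 features differed in this window, in which the values of DXC arrays were more spread (mean SD over features 1.65, 12 arrays, 0 to 9 h) than those of DX arrays (1.52, 12 arrays).

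In the middle window, 12 to 24 h, genes that were lower in DXC outnumbered those that were higher. ACO1, which encodes an enzyme of the last step of ethylene synthesis, fell by 2.41 (SE 0.38; adjusted p = 0.000245), and at 12 h stood at 6.07 ± 0.63 in DXC against 9.28 ± 0.23 in DX, a 9.26-fold difference. ACO1 was called whichever experiment was left out. The class III peroxidase gene LOC4339222, also named PRX74, fell by 2.33 (adjusted p = 0.00274, but 0.25 without experiment 2 and 0.18 without experiment 3). HK1, a histidine kinase gene, rose by 1.82 (SE 0.35; adjusted p = 0.00273), and CBL4, which encodes a calcineurin B-like calcium sensor, by 1.53 (adjusted p = 0.00485). Both were at their largest difference before the window, HK1 at 9 h (6.61-fold) and CBL4 at 6 h (7.63-fold), and neither was called in the window without experiment 2 (adjusted p = 0.256 and 0.424), nor HK1 without experiment 3 (0.0917).

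LOC9271993 was still 17.8-fold higher (adjusted p = 1.07e-09), followed by LOC4351404 (2.41), LOC4330584 (2.19), LOC4324857 (2.09), LOC9269942 (2.08), LOC4350632 (1.72), LOC4330827 (1.66) and LOC4331432 (1.39). For LOC4330827 the larger part lay at 0 h, and with no subtraction of 0 h its difference was 0.27 and not called (adjusted p = 0.432). The lower genes included LOC4339602, annotated as a long noncoding RNA (-2.35), LOC4349331 (-2.24), LOC4342139 (-2.09), LOC9271064 (-2.07), LOC4337187 (-2.04), LOC4347763 (-1.96), LOC4324060 (-1.94) and LOC4347897 (-1.87). For LOC4349331 the larger part lay at 0 h, where DXC was higher by 1.34, and for LOC4339602 in a rise of DX by 1.34. In all 127 features were called, 48 higher and 79 lower, and 227 with the experiment as a block (72 higher, 155 lower). Leaf photosynthesis genes had a median difference of -0.53 in the same window. After quantile normalization the balance turned, with 49 higher and 37 lower among 86. With array sets as a random block 48 were called, 21 higher and 27 lower, and LOC4330827, LOC4339602 and LOC4324060 were not (adjusted p = 0.171, 0.173 and 0.0775). Without experiment 1 the count was 47, without experiment 2 it was 5 and without experiment 3 it was 19; of the 20 named genes 10, 2 and 7 stayed called. In a fit of only 0 h and the hours of this window 5 of the 20 were not called, LOC4330584 (adjusted p = 0.105), LOC4350632 (0.0591), LOC4330827 (0.148), LOC4339602 (0.0579) and LOC4324060 (0.101).

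In the late window, 27 to 45 h, the lower genes again prevailed. LOC4339602 had a difference of -3.17 (SE 0.54; adjusted p = 0.000685), the larger part of which was a rise in DX from 6.95 ± 0.64 at 0 h to 8.60 ± 0.04, while DXC went from 7.71 ± 0.60 to 6.19 ± 0.36. LOC4347897 fell by 2.41 (adjusted p = 0.000122). Their calls were lost without experiment 2 (adjusted p = 0.0836 and 0.0608), that of LOC4339602 also without experiment 1 (0.0579) and that of LOC4347897 without experiment 3 (0.0518). LOC9271993 remained 6.97-fold higher (adjusted p = 0.000122), with 6.53 ± 0.19 in DXC at 45 h against 4.06 ± 0.17 in DX. MADS17, a MADS-box transcription factor gene, rose by 0.98 (adjusted p = 0.00974) and LOC4344909 by 1.10 (adjusted p = 0.0365), both not called when any 1 experiment was left out (adjusted p from 0.0608 to 0.358).

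The remaining lower genes were LOC4349331 (-2.35), LOC9271064 (-2.25), LOC4339222 (-2.08), LOC4347763 (-1.81), LOC4323864 (-1.72), LOC4336616 (-1.64), LOC4324560 (-1.62) and LOC4347224 (-1.60). For LOC4347224 the larger part was a rise of 0.90 in DX, with a change of -0.69 in DXC. For LOC4349331 and LOC4336616 the larger part lay at 0 h, where DXC was the higher line. LOC4336616 was at 5.27 ± 0.10 in DXC and 4.09 ± 0.31 in DX at 0 h and at 3.25 ± 0.14 and 3.70 ± 0.16 late. LOC4349331 was at 6.30 ± 0.71 and 4.95 ± 0.35, then 4.06 ± 0.31 and 5.06 ± 0.34. The remaining higher ones were LOC4351404 (2.14), LOC4330827 (1.82) and LOC4324857 (3.47-fold). With no subtraction of 0 h the late difference of LOC4330827 was 0.43 and not called (adjusted p = 0.0554). LOC4324857 was at 5.69 ± 0.44 in DXC and 4.78 ± 0.28 in DX, against 4.21 and 5.09 at 0 h. LOC4341605 (1.29), LOC4333605 (1.28), LOC4333008 (1.22) and LOC4326867 (0.97) were called higher, but their largest difference at any hour was at 0 h, where DXC was the lower line. In all 91 features were called, 24 higher and 67 lower, and leaf photosynthesis genes had a median difference of -0.46. The count was 175 with the experiment as a block (45 higher, 130 lower), 53 after quantile normalization, and 32 with array sets as a random block (8 higher, 24 lower), where LOC4330827, LOC4324857, LOC4333605, MADS17, LOC4326867, LOC4336616 and LOC4347224 were not called (adjusted p from 0.0597 to 0.2). Without experiment 1 it was 30, without experiment 2 it was 1 and without experiment 3 it was 4; of the 20 named genes 10, 0 and 2 stayed called. Without experiment 2 the difference of LOC4330827 was 1.04 and that of LOC4324857 was 1.34. In a fit of only 0 h and the hours of this window LOC4333605 (adjusted p = 0.0657) and LOC4344909 (0.104) were not called. Without experiment 2 the adjusted p of LOC9271993 was 0.0608.

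Of the 7 crown root regulators on the fixed list, WOX11, a WUSCHEL-related homeobox gene that promotes crown root growth, was the one called in a window. Its early difference of -0.84 was not called (adjusted p = 0.166), but was with the experiment as a block (0.0377) and with array sets as a random block (0.00213). It fell by 1.23 in the middle window (SE 0.23; adjusted p = 0.00273) and by 1.25 in the late window (adjusted p = 0.00227). Part of this came from 0 h, where its level was 5.79 ± 0.41 in DXC and 5.27 ± 0.06 in DX; with no subtraction of 0 h the differences were -0.71 and -0.72. The call in both windows was lost without experiment 2 (adjusted p = 0.3 and 0.33) or experiment 3 (0.359 and 0.182). QHB, a homeobox gene of the root quiescent centre, had an early difference of 0.80 (adjusted p = 0.148, and 0.00271 with array sets as a random block). At single hours it was 2.27-fold higher in DXC at 6 h (5.57 ± 0.36 against 4.39 ± 0.40; adjusted p = 0.000138) and higher by 0.92 at 9 h (adjusted p = 0.00738). IAA23 was higher by 1.13 at 6 h (adjusted p = 0.00147) and hox14 by 1.03 at 9 h (adjusted p = 0.0351). The 6 h call of QHB was lost without experiment 2 (adjusted p = 0.0761), that of IAA23 without experiment 3 (0.0928) and that of hox14 whichever experiment was left out.

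The other members, CKX4, OsRR2 and WOX10, were called in no window and at no hour from 3 to 45 h; their early differences were -0.23, -0.17 and 0.13. Adjusted over the list alone, 3 of 7 members were called early (QHB and hox14 higher, WOX11 lower), 3 in the middle window (hox14 and WOX10 higher, WOX11 lower) and 1 late (WOX11). The crown root list as a whole was not called in any window (adjusted p = 0.689, 1 and 0.893 in early, middle and late order), nor was the WOX family (8 features; 0.228, 0.82 and 0.689), of which 0, 1 and 1 members were called and 2, 1 and 1 adjusted over the list alone.

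Of 28 DNA replication features 26 were above 0 early, with a median difference of 0.37 (0.22, 0.30 and 0.52 in the 3 experiments; adjusted p = 5.47e-07, and adjusted p = 0.67 with an estimated correlation). RFC1 was the member called, also adjusted over the list alone, while MCM5 (0.47), RFC4 (0.71) and ORC4 (0.65) missed the threshold. With array sets as a random block MCM5, RFC4 and ORC4 were called too (adjusted p = 0.0351, 0.0151 and 0.0385). Cytosolic ribosomal protein genes were higher early (21 of 21 features above 0, median 0.29; adjusted p = 0.000755) and lower in the middle window (20 of 21 below 0, median -0.40; adjusted p = 0.000522), with 0 members called by limma and 0 adjusted over the list alone in both, and 2 and 5 with an unadjusted p under 0.05; the adjusted p with an estimated correlation was 0.71 and 0.681. Their early median was -0.12 in experiment 2, and the early call was lost without experiment 3 (median 0.01, adjusted p = 0.701). Core histones were lower in the middle window (9 of 10, median -0.45; adjusted p = 0.0206, and adjusted p = 0.67 with an estimated correlation), with 0 members called, 0 adjusted over the list alone and 2 with an unadjusted p under 0.05; this call was lost without experiment 3 (adjusted p = 0.152) and with no subtraction of 0 h (0.221). After quantile normalization the middle calls of the ribosomal list (median -0.09, adjusted p = 0.125) and of the histones (median -0.20, adjusted p = 0.177) were lost.

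**Figure D3:**
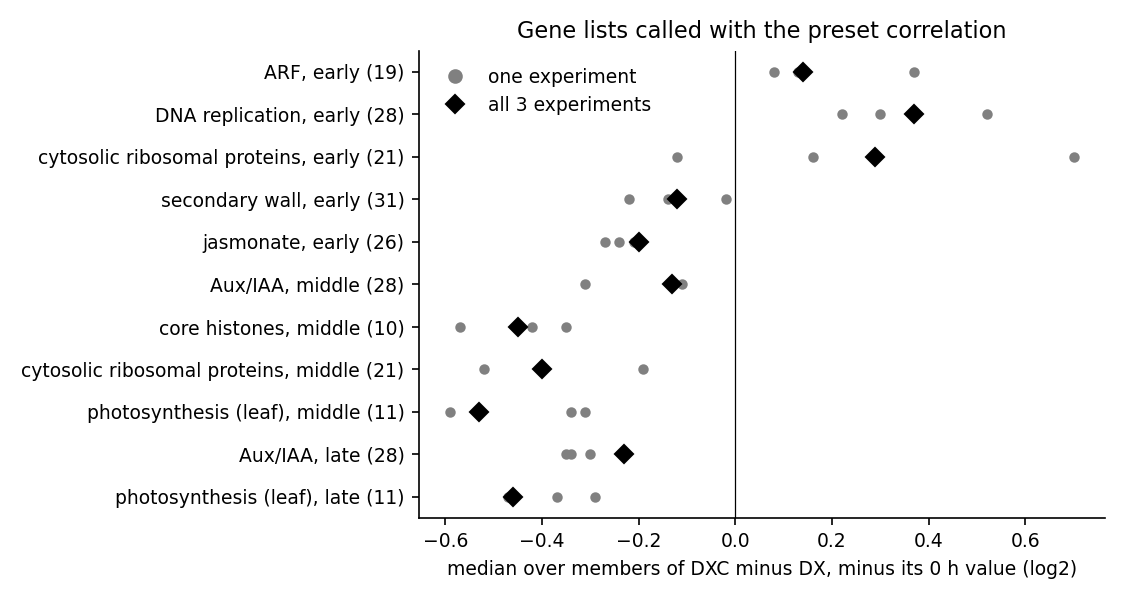
Median over list members of the log2 difference DXC minus DX, minus its 0 h value (x axis), for the 11 lists and windows called with the preset correlation (y axis; number of features in brackets). Grey points are the 3 experiments and black diamonds the value over all of them; the DNA replication list stood at 0.37 and leaf photosynthesis in the middle window at -0.53.

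The Aux/IAA list, repressors of auxin response, was called lower in the middle (18 of 28 below 0, median -0.13; adjusted p = 0.0122) and late window (18 of 28, median -0.23; adjusted p = 0.000755), with an adjusted p = 0.534 with an estimated correlation in both. IAA15 fell by 0.93 and 0.85 (adjusted p = 0.00113 and 0.00298), of which -0.49 and -0.42 lay in the windows and the rest at 0 h, where DXC was higher by 0.43. IAA24 fell by 0.71 in the middle window (adjusted p = 0.0332), while IAA31 fell by 1.05 and IAA1 (LOC4334069) by 1.04 in the late window; at 0 h DXC was higher by 0.21, 0.26 and 0.31 in these 3 genes. There were 2 members called in the middle window (6 adjusted over the list alone) and 3 late (12 adjusted over the list alone, 10 of them lower and IAA26 and IAA8 higher, by 0.66 and 0.50). The higher values of IAA26 and IAA8 came almost wholly from 0 h, since late levels were 3.31 in DXC and 3.29 in DX for IAA26 and 5.25 and 5.16 for IAA8. With the experiment as a block IAA12 was called lower in the middle and late window too (adjusted p = 0.0149 and 0.0405). So were IAA31 in the middle (0.0279) and IAA24 in the late window (0.0271). With array sets as a random block IAA15 stayed called, but IAA24 (adjusted p = 0.189), IAA31 (0.0744) and IAA1 (0.11) were not. Whichever experiment was left out, IAA24, IAA31 and IAA1 were not called (adjusted p from 0.0731 to 0.456), nor was IAA15 late (0.0579 to 0.278). In the middle window IAA15 was called only without experiment 1. The middle call of the list was lost without experiment 1 (adjusted p = 0.175). ARF genes, which encode the transcription factors that Aux/IAA proteins bind, were higher early (16 of 19, median 0.14; adjusted p = 0.0122, and adjusted p = 0.67 with an estimated correlation); 0 were called and 2, ARF2 (LOC4325895) and ARF14, adjusted over the list alone, with 3 under an unadjusted p of 0.05. ARF2 was called with the experiment as a block (adjusted p = 0.0472). That ARF list call was lost without experiment 3 (adjusted p = 0.236) and without dim features (adjusted p = 0.0933).

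Leaf photosynthesis genes, markers of green tissue in the sample, were lower in the middle (10 of 11, median -0.53; adjusted p = 0.000755) and late window (10 of 11, median -0.46; adjusted p = 0.000522), with an adjusted p = 0.67 with an estimated correlation in both and 0 members called, 0 adjusted over the list alone and 4 and 5 with an unadjusted p under 0.05. With no subtraction of 0 h the medians were -0.09 and -0.10 and both calls were lost (adjusted p = 0.422 and 0.195). Jasmonate genes were lower early (21 of 26, median -0.20; adjusted p = 0.0111, and adjusted p = 0.67 with an estimated correlation), as were secondary wall genes (29 of 31, median -0.12; adjusted p = 0.019, and adjusted p = 0.534 with an estimated correlation). Of both lists 0 members were called and 0 adjusted over the list alone, while 1 jasmonate and 2 secondary wall features had an unadjusted p under 0.05. The jasmonate call was lost without experiment 1 (adjusted p = 0.163), and that of the secondary wall list without experiment 1 (0.187), after quantile normalization (0.0662) and without dim features (0.204).

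The other lists were not called in any window, and their lowest adjusted p follows with the window. For auxin and cytokinin these were GH3 and SAUR 0.136 (early, 1 of 10 called, 2 adjusted over the list alone), auxin transport 0.165 (early), type-A response regulators 0.195 (late) and cytokinin metabolism 0.165 (early). Gibberellin metabolism had 0.594 (middle). For the cell cycle and organ identity they were mitotic cyclins and CDKB 0.073 (middle; 0.0326 with the experiment as a block), D-type cyclins 0.145 (middle), HD-ZIP and ROC 0.223 (late), SCARECROW and SHORT-ROOT 0.483 (middle) and KNOX 0.262 (late). For the wall they were wall loosening 0.828 (late) and class III peroxidases 0.073 (late; 0.0413 with the block), and for polarity ROP signalling 0.073 (late; 0.0413 with the block). For stress they were heat shock 0.142 (middle), hypoxia 0.0842 (early) and pathogenesis-related genes 0.483 (middle). Single members were called nonetheless. Hox21 had differences of -0.89 in the middle (adjusted p = 0.00125) and -0.69 in the late window (adjusted p = 0.0255, and 0.098 with array sets as a random block). Its middle call was lost without experiment 1 or 2 (0.0764 and 0.235) and its late call whichever experiment was left out (0.157 to 0.395). Adjusted over the list alone, 5 HD-ZIP and ROC features were called in the middle and 4 in the late window, 5 of 11 KNOX features late (2 higher, 3 lower) and 5 and 1 of 47 wall loosening features in the middle and late window. In the same way there were 2, 1 and 2 for cytokinin metabolism in window order, 2 and 2 class III peroxidases and 1 and 1 D-type cyclins in the middle and late window, 1 heat shock feature in the middle and 2 hypoxia features in the late window. Seed storage and amylase genes, markers of seed remains, had 0.145 (early), and the clock list 0.073 (late). Of 84 list tests 11 were called, 3 higher and 8 lower, 14 with the experiment as a block and 11 with array sets; 0 were called with an estimated correlation, where the lowest adjusted p was 0.534 and 6 tests had an unadjusted p under 0.05. Median, mean and test had the same sign in the 11 called lists and differed in some of the others.

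Hour by hour, with no subtraction of 0 h, called differences between the lines were concentrated at 6 and 9 h. At 0 to 9 h DXC arrays were also more spread than DX arrays (mean SD over features 1.65 against 1.52). Without that subtraction the early window called 22507 features. The share of the spread in the hourly counts was not separated. At 3 h 222 features were called, at 6 h 1259 (917 higher in DXC), at 9 h 902 (794 higher), at 12 h 283, at 24 h 51, at 33 h 21 and at 45 h 70. With the experiment as a block the counts at 3, 6 and 9 h were 891, 2829 and 1602, and with array sets as a random block 1127, 2990 and 1815. Lower in DXC at 6 h were 342 in the main fit, 985 with the experiment as a block and 1173 with array sets. LOC9271993, LOC4331398 and LOC9266913 were among 6 features called at all 15 hours from 3 to 45 h, the other 3 having no gene symbol. Of these 6, all but LOC9271993 (-0.42 at 0 h, mean 3.31 later) had a difference of similar size already at 0 h. LOC4351404 was called at 14 hours, and MADS17, HK1 and LOC4347897 at 10. In all 2287 features were called at 1 or more hours, 1665 of them at 1 hour only; 5025 were called at 1 or more hours with the experiment as a block and 4972 with array sets as a random block. Without experiment 1 the count was 504, without experiment 2 it was 3110 and without experiment 3 it was 467.

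**Figure D4:**
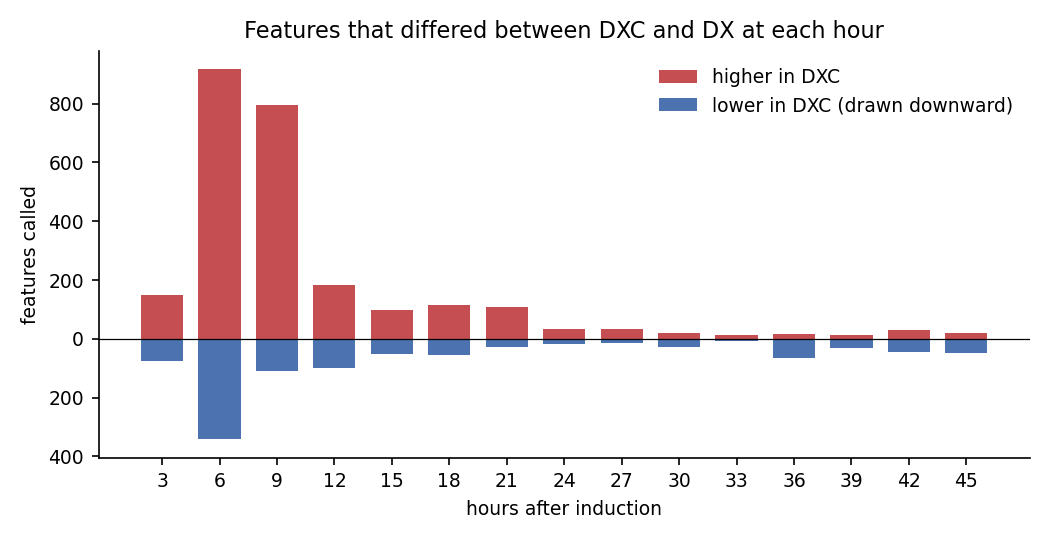
Number of features that differed between DXC and DX (y axis; adjusted p under 0.05 over all features and hours) at each hour after induction (x axis), with features higher in DXC drawn upward and lower ones downward. Calls were most numerous at 6 h (917 higher, 342 lower) and 9 h (794 higher, 108 lower). The 0 h difference was not subtracted.

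A different course over time in the lines was found for 355 features by the interaction test, 769 with the experiment as a block and 406 with array sets as a random block. The count was 67 without experiment 1, 70 without experiment 2 and 100 without experiment 3. The change of the line difference between the early and the late window was tested as well, after the data were seen. LOC4339602 had the largest such change, from a line difference of 0.21 early to -2.41 late (change 2.62, SE 0.35; adjusted p = 1.59e-07), followed by LOC9271993, from 4.78 to 2.38 (change 2.39; adjusted p = 4.01e-09). LOC4349090 went from 2.11 to -0.02 and LOC4347898 from 0.45 to -1.68. For this contrast 16622 features were called, 8738 higher and 7884 lower early, and 5499 with array sets as a random block. With the experiment as a block it was 18340, without experiment 1 it was 4084 and without experiment 3 it was 7426. The mean SD over features was 1.65 in DXC and 1.52 in DX at 0 to 9 h, but 1.53 and 1.53 at 24 to 33 h and 1.57 and 1.58 at 36 to 45 h. At 0 h it was already 1.630 to 1.652 in DXC and 1.506 to 1.603 in DX. After quantile normalization 12923 features were called, and without dim features 8005 were called higher and 3441 lower early.

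Within DX, the line without CRL1, the 5 genes with the largest range over time had their highest means at 39 to 45 h. LOC4326518 ranged over 3.58 log2 units, from 5.62 ± 0.92 at 6 h to 9.20 ± 0.29 at 39 h (adjusted p = 0.0174), LOC4327172 over 3.40 (adjusted p = 0.00184) and the chitinase gene Cht-3 over 3.02, from 5.30 ± 0.58 at 6 h to 8.33 ± 0.35 at 39 h (adjusted p = 0.0247). LOC4325832 ranged over 2.61 and LOC4350388 over 2.48 (adjusted p = 1.28e-08), the one of these 5 that was called with array sets as a random block (adjusted p = 0.000668). In DX 136 features were called for time, but 5 of 100 reorderings of the arrays called as many or more (highest other 1298), so that chance could not be excluded. The count was 343 with the experiment as a block, 271 after quantile normalization and 21 with array sets. Without experiment 1 it was 11, without experiment 2 it was 1736 and without experiment 3 it was 8. LOC4326518 was not called when any 1 experiment was left out (adjusted p from 0.0917 to 0.598), nor without experiment 1 or 3 were LOC4327172 (0.57 and 0.161), Cht-3 (0.641 and 0.62) and LOC4325832 (1 and 0.14), while LOC4350388 was called whichever was left out (0.00076 to 0.00229).

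Within DXC the largest ranges were those of LOC9271993 (5.87), LOC4330584 (5.12) and the expansin gene EXPB15 (4.88, from 9.16 ± 1.15 at 3 h to 4.28 ± 0.44 at 42 h; adjusted p = 0.000154), by the rule for DX, carried over to DXC after the data were seen. EXPB15 was not called without experiment 2 (adjusted p = 0.226). In DXC 1969 features changed with time, 4154 with the experiment as a block and 1952 with array sets; without experiment 1 it was 390, without experiment 2 it was 332 and without experiment 3 it was 7370. There were 34 features called in both lines, against 7.3 for independent lists of these sizes. Both tests used the same estimate of the spread per feature, so the lists were not independent. A shared course was therefore not shown.

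Genes of the circadian clock changed by less than 1 log2 unit over the 45 h. In DX the hourly means of GI, PCL1, PRR1, PRR73, PRR37, LHY and PRR95 ranged over 0.62, 0.72, 0.54, 0.78, 0.66, 0.59 and 0.33 log2 units, and 0 of the 7 were called by limma (lowest adjusted p = 0.0791, GI), while 5 had an unadjusted p under 0.05. The median range of the 7 in DX was 0.62, against 0.51 for all features. The 8 hourly means of the first day and those of the second had correlations from 0.49 to 0.88 in DX (median 0.80; 0.47 for all features) and from -0.50 to 0.48 in DXC (median 0.10; -0.10 for all features). In DXC the ranges were 0.38, 0.76, 0.43, 0.53, 0.87, 0.40 and 0.28 in the same order. PRR37 was called there, with 6.58 ± 0.39 at 9 h and 5.71 ± 0.26 at 30 h (adjusted p = 0.0472, but 1 without experiment 1 and 0.475 without experiment 2), and at 9 h it was 2.29-fold higher in DXC than in DX (adjusted p = 0.00089, but 0.0949 without experiment 1 and 0.354 without experiment 3).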

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

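The tests of array sets and of the early against the late window were chosen only after the results were seen.

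Effects that differed between time points stood out by a test of the difference itself. A line by time interaction was called for 355 features, and the line difference changed between the early and the late window for 16622 features. The changes with the largest size in that contrast were those of LOC4339602 (2.62) and LOC9271993 (2.39). DXC arrays were more spread than DX arrays at 0 to 9 h, already before induction. Later the means of the lines were alike, but single experiments differed in both directions. At 24 to 33 h the mean SD was 1.46 in DXC and 1.58 in DX in experiment 2, and 1.64 and 1.54 in experiment 3. After quantile normalization the early against late contrast called 12923. Without dim features it called 8005 higher and 3441 lower early, against 8738 and 7884 with all features. Mostly lower calls were thus lost with the dim features, which a wider spread of DXC arrays would also give. The share of the spread in the calls was not separated. For the interaction 1 of 100 splits of the lines within each hour, the real one, gave as many, and the highest other gave 27. Splits that swap the lines within experiment and hour keep the pairing of the experiments. There it was also 1 of 100, and the highest other gave 254. Simulated set effects with no change gave 32 interaction calls, against 355 in the data. Each kind of split draws the lines anew at every hour, which breaks up the array sets. Chance was therefore excluded for the interaction only for arrays that do not deviate together in sets. The early against late contrast had the same share and the same limit (1 of 100, the highest other 11992, and 15227 among the paired splits). That a random split can call so many points to a structure of the samples.

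Arrays of 4 consecutive hours of 1 line and experiment deviated together. Adjacent hours correlated by 0.38 within sets and by 0.12 across set boundaries, but the boundaries had been seen in the same arrays. With boundaries found in 1 line and tested in the other, the 3 gaps with the lowest correlation in DX did not pass in DXC (difference 0.22, one-sided exact p = 0.0593 over 455 choices of 3 gaps), nor those of DXC in DX (0.03, exact p = 0.424). Of the variance of array SDs 93.1% lay between the 24 sets and 22.6% by line and hour, but the sets had been seen in the same arrays. Slow change over hours within a culture and a common handling of 4 arrays, which no label names, were therefore both left open. Swapping the lines for whole sets gave as many features in 1 of 100 splits for the middle window (real 127, highest other 116) and in 1 of 100 for the late window (real 91, highest other 57). Sets alone were thus argued against as the whole source of these 2 counts, and remain open as a part of them. For early against late it was 2 of 100 (real 16622, highest other 19665). Since another swap called more than the real lines, no such conclusion was drawn there. That count fell to 5499 with sets as a random block, and simulated set effects with no change gave 571 calls. For the early window such swaps had too few distinct outcomes to tell.

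For the windows themselves, splits of the lines within each hour gave as many features in 2 of 100 draws early (real 122, highest other 475), 1 of 100 in the middle window (real 127, highest other 6), 1 of 100 late (real 91, highest other 27) and 1 of 100 for any hour (real 2287, highest other 809), the real one included. Splits that swap the lines within an experiment and hour keep the pairing, and gave higher counts. There 3 of 100 gave as many early (highest other 2005, which points to the structure of the arrays). It was 1 of 100 in the middle window (80), 1 of 100 late (38) and 1 of 100 for any hour (1515). Both kinds of split draw the lines anew at each hour, which breaks up the sets of 4 hours. They therefore exclude chance only for arrays that do not deviate together in sets, and for the early window chance was left open. For the middle and late windows the swaps of whole sets above, which keep the sets, also gave as many in 1 of 100. At 0 h the 10 splits of the 6 arrays are too few for a share under 0.05; the real split gave 10 features and the highest other 3. For the time effect in DXC 1 of 100 reorderings of the arrays gave as many (real 1969, highest other 247). For DX chance could not be excluded, since 5 of 100 gave as many (real 136, highest other 1298), although 2 of 100 reorderings of whole sets did (highest other 1601).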

How the results depend on the processing

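The array sets and the contrast of early with late windows were chosen only after the results were seen. Centring of array medians, leaving out dim features and eBayes without the trend moved no total count over 1.5 times. No named value changed sign in any setting. By direction, leaving out dim features cut the lower early against late calls from 7884 to 3441, and the higher ones from 8738 to 8005. The balance of the middle window turned under quantile normalization. Another scale was not tried, since values were already log2, and the annotation tied no feature to CRL1. With the experiment as a block the counts were 19 at 0 h, 769 for the interaction, 184 early, 227 middle, 175 late, 5025 at any hour, 343 over time in DX and 4154 in DXC. Quantile normalization gave 53 late and 271 in DX, and a middle count of 86 (49 higher, 37 lower, against 48 and 79). With no subtraction of the 0 h difference the counts were 22507 early, 2196 middle, 1878 late and 19 lists; with only the hours in the contrast 3 at 0 h and 46 early. Array sets as a random block gave 36 at 0 h, 802 early, 4972 at any hour, 48 middle, 32 late, 5499 early against late and 21 in DX, and as a fixed block 1271 early. Leaving out 1 experiment, which leaves 2 arrays per group, gave from 0 to 6 at 0 h, 67 to 100 for the interaction, 4 to 55 early, 5 to 47 middle, 1 to 30 late, 467 to 3110 at any hour, 4084 to 16145 early against late, 8 to 1736 in DX, 332 to 7370 in DXC and 9 to 14 lists. The cause of these changes was not tested. The last setting also has fewer arrays, but with it some counts rose, up to 3110 at any hour, 1736 in DX and 7370 in DXC. Of 68 values of named genes, 35, 60 and 46 lost their call without experiment 1, 2 and 3, 11 after quantile normalization and 14 with array sets; so did 21 of 63 with only the hours in the contrast and 7 of 58 with no subtraction of 0 h. Signal over background is not known, since no detection call was used here.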

Other observations

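The DNA replication list was picked for testing after its result was seen. The tests of the clock genes, of the 24 h cosine and of neighbouring genes were chosen only after the results were seen.

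Genes next to each other changed together in a few cases. Neighbours here are next to each other in the RefSeq gene order of assembly ASM3414082v1 among the 24160 placed genes with an array feature. Genes without a feature may lie between them. LOC9268927, at 8.86 ± 0.40 in DXC at 9 h and 11.5-fold above DX, neighbours LOC4330584, and both were called higher in the early window. LOC4347224 neighbours ACO1, and both were lower in the middle and in the late window, as were the neighbours LOC9271064 and LOC4339878. For LOC4347224 the larger part of the late value was a rise in DX. Its late call was lost with array sets as a random block (adjusted p = 0.0597) and whichever experiment was left out (0.0923 to 0.281). Among genes lower in the middle window 2 neighbouring pairs were found, against a mean of 0.17 in 10000 random sets of 64 genes (one-sided permutation p = 0.0118, adjusted p = 0.0354 over 6 sets), and the same 2 pairs were found among those lower late, against 0.14 (p = 0.0091, adjusted p = 0.0354), which is therefore no second finding. The 2 pairs among 106 genes higher early did not pass (one-sided permutation p = 0.0811, adjusted p = 0.162).

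The DNA replication list was higher in DXC in the early window, with a median of 0.37. A bias that depends on intensity was argued against, since the medians of 10000 lists matched on mean value had an upper limit (two-sided, level 0.05) of 0.15 and 0 of them were as high, and so were differences between arrays in their distribution of values, since the median was 0.30 after quantile normalization. Swaps of the lines within experiment and hour gave a median as large in 1 of 100 draws (highest other 0.36), but splits of the lines within each hour without regard to experiment did so in 7 of 100. With an estimated correlation the list was not called (adjusted p = 0.67). Whether replication genes rose by induction was therefore not decided, and co-regulation among the 28 members was left open.

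The clock genes changed little over 45 h. A strong rhythm hidden by hour labels that do not belong to the arrays was argued against. Shuffled genes of strong rhythm would spread widely over single arrays, whereas the median SD of the 7 features over all 96 arrays was 0.27, the same as that of all features. Whether the labels belong to the arrays was not decided, since with a damped rhythm the SD would be low under any labels. Values near the low end of the arrays were argued against for GI, PRR1 and PRR73 (means 8.82, 7.98 and 7.10). All 3 were above the upper quartile of the features in each of the 96 arrays (5.96 at most). For PCL1, PRR37, LHY and PRR95 (6.30, 5.84, 5.41 and 4.89), of which 0 were above it in each array, this was left open. The background of the 7 features was not measured, so a signal over it was not shown for any of them. A cosine of 24 h was called for 6 of 7 clock features in DX, with amplitudes up to 0.32, but also for 12958 features in all, and with array sets as a random block for 0 of 7 and for 1 feature in all. In DXC it was called for 0 of 7 (adjusted p from 0.463 to 0.98) and for 102 features in all. The clock genes of DX followed a similar course on both days (correlations from 0.49 to 0.88, median 0.80, against a median of 0.47 for all features), while those of DXC had correlations from -0.50 to 0.48 (median 0.10, against -0.10 for all features). Much of the gap between the lines was thus shared by all features; the difference between the lines was not tested. A damped rhythm and the array sets were left open.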
